A study of Drosophila melanogaster with 4 samples.

How the data were processed

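Chromatin from larvae of the third instar of Drosophila melanogaster, strain Oregon-R, was examined by ChIP-seq with a rabbit polyclonal antibody against histone H3 acetylated at lysine 27 (H3K27ac). Per the labels' protocols, homogenised tissue was fixed in formaldehyde, chromatin was released from nuclei by detergent and sonication, and antibody complexes were collected on beads, washed, and freed of RNA, protein and cross-links. The labels name 4 samples, which are 2 ChIP replicates and 2 input samples. Both ChIP replicates have a list of enriched regions, and a further list covers the replicate set. No region list of the input samples was used here. The labels do not say whether the replicates came from separate collections of larvae, so the SD between them may be technical. The p-values compare positions and windows along the genome, not animals.

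Per the file headers, all 3 lists give positions on FlyBase release 5. Bowtie 0.12.7 is named in the submitters' processing notes, without its role. The program that called the regions, its threshold, the use made of the input and the way the replicates were combined are not given in the sources used here. Each deposited region has a start, an end and 1 signed score, and the scores are the authors' own values, on a log2 scale. That base is read from the deposited values and is not stated. Each score was compared with the most common score of its list, and the difference was tested as the log of a ratio of whole numbers, with a denominator of at most 400, a numerator of at most 1600 and a relative tolerance of 1e-09. With base 2, 36.6% of the scores of replicate 1, 52.9% of replicate 2 and 34.6% of the replicate set passed, and with base e or base 10 at most 0.479% of any list did. Differences between scores are therefore given as log2 differences, and the constant behind the zero of the scale is unknown. The depth of sequencing is also unknown, since the lists hold no read counts, and intervals given for shares of regions cover counting error only. The end of 1 region of the replicate set is written in scientific notation and was read as 17000000.

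The 3 lists were read with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Regions named as enriched were used, and 3 regions of the replicate set named as depleted were kept apart. A both-replicate region is a stretch of bases that lies inside a region of replicate 1 and a region of replicate 2. It carries the mean of both scores. Overlap means at least 1 bp shared. Chance overlap was taken from 1000 circular shifts of replicate 2 along each sequence, which keep the widths and the clustering of regions, with a one-sided permutation p that cannot go below 0.001. Agreement of scores and widths was described by correlations across regions, which are not independent replicates, so these have no p-value. Each replicate 1 region was paired there with the replicate 2 region that shares most bases with it.

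The X was compared with the 5 autosomal arms (2L, 2R, 3L, 3R and 4) over 500-kb windows, where a window at the end of an arm was kept if it filled at least 50% of that length. The test was a two-sided permutation test of the difference in window means with 100000 resamples, which cannot give a p below 1e-05, and Benjamini-Hochberg adjustment over 4 measures. Neighbouring windows resemble each other, so the block of X windows was also rotated along the concatenated windows, and the rotations with a difference at least as large in either direction were counted. The rotations include the unrotated position, and nearby rotations share most of their windows. Their share is therefore a description and not a p-value. Covered share and region number were chosen before the data were examined, as were the lists of named regions, which are the 10 widest both-replicate regions and the 5 highest scores of the replicate set, by position only. The comparisons of score and width on the X and the rotation were added after. The overlap counts and the window test were tested on simulated data. With 69.2% of 5501 regions copied into a second list, the script recovered 69.2%. The copies kept their positions and widths, so this tests the counting only, and not partial overlaps or divided regions. The window test called 4% of 200 simulated sets of 241 windows without a difference and 86% of those in which the X was raised by 5 percentage points. The simulated windows were drawn independently, unlike neighbouring windows of the data, so these rates may not hold for the data.

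Alternatives were each replicate alone, the replicate-set list, the higher-scoring 50% of each list, reciprocal overlap of 50%, random placement, other window sizes and other shares of widest regions. Tests of 20 gene lists, of promoters and of genes under wide regions had been planned on condition that an annotation of the same build was at hand. The gene table used for this work is on release 6, so its coordinates were not mixed with those of the regions, and genes were not analysed here.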

Results

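The data describe where H3K27ac, a histone mark of active promoters and enhancers, lay in the genome of wild-type Drosophila larvae of the third instar. The samples were 2 ChIP replicates and 2 inputs, and the inputs were not analysed here. The 2 ChIP replicates listed 5501 and 5426 enriched regions, a mean of 5464 ± 53.0 (SD, n = 2). These regions covered 26.0 ± 1.08 Mb (SD, n = 2), which is 18.6% ± 0.772 of the sequences of FlyBase release 5 without the sequence set named Uextra, on which no region was listed. The median region was 3138 ± 40.0 bp wide (SD, n = 2). Each region carries a score given by the authors on a log2 scale, with a median of 0.84 in replicate 1 and 0.83 in replicate 2. Regions ranged from 1301 bp to 64.7 kb in replicate 1 and from 1301 bp to 63.9 kb in replicate 2. The gap between neighbouring regions had a median of 5129 bp in replicate 1 and 5599 bp in replicate 2. The list of the replicate set held 6270 enriched regions over 30.5 Mb. No read counts accompany the lists, so the depth behind each region is unknown.

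The first comparison asks how far the replicates place the mark at the same sites. Of the replicate 1 regions, 4879 of 5501 (88.7%, 95% Wilson interval 87.8 to 89.5) overlapped a region of replicate 2, and of the replicate 2 regions, 5086 of 5426 (93.7%, 93.1 to 94.3) overlapped a region of replicate 1. Shared bases made up 84.1% of the bases listed in either replicate. With replicate 2 shifted along the chromosomes, 34.4% ± 0.838 of the replicate 1 regions overlapped and 12.0% ± 0.472 of the bases were shared (SD, 1000 shifts). None of the shifts reached the observed values, which gives the smallest p these permutations allow, 0.001, for each measure. The both-replicate regions numbered 5281 and covered 23.8 Mb, or 17.0% of the sequences. They are stretches of overlap, and a wide region of 1 replicate can give several of them. The shortest was 6 bp, and 110 were under 1000 bp, narrower than any region of either replicate.

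Regions that 1 replicate listed alone had lower median widths and scores than shared regions. In replicate 1, the 622 unshared regions had a median width of 1613 bp and a median score of 0.47, beside 3534 bp and 0.93 for the 4879 shared regions. In replicate 2, the 340 unshared regions had a median width of 1586 bp and a median score of 0.50, beside 3283 bp and 0.87 for the 5086 shared ones. In the lowest 10% of scores, 57.5% of the replicate 1 regions and 84.9% of the replicate 2 regions were shared. The next 10% of replicate 2 had a lower share, 78.4%. In the highest 10% the share was 99.6% in both replicates (549 of 551 and 541 of 543), and the highest score of replicate 1, 3.90, belonged to an unshared region. Scores of the 4879 pairs of overlapping regions had a Spearman rho of 0.91 and a Pearson r of 0.93 across regions, and their widths had a Spearman rho of 0.86. Wider regions had higher scores, with a Spearman rho between width and score of 0.83 in replicate 1 and 0.82 in replicate 2.

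**Figure D1:**
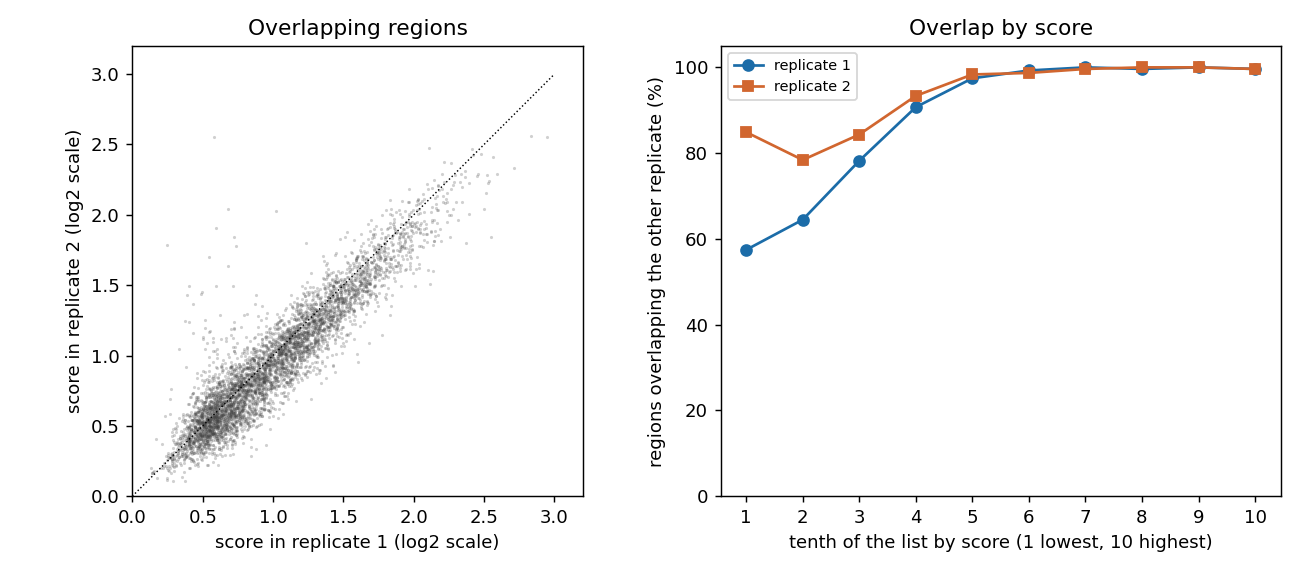
Left, score of each of the 4879 pairs of overlapping regions in replicate 1 (x axis) and replicate 2 (y axis), both on a log2 scale, with the dotted line marking equal scores. Right, percent of the regions of each replicate that overlap the other, in 10 classes of each list by score. The share was 57.5% (replicate 1) and 84.9% (replicate 2) in the lowest class and 99.6% in the highest.

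The list of the replicate set was set beside the replicates. Of its 6270 regions, 4510 (71.9%) overlapped a region of both replicates and held 90.5% of its bases. A further 576 overlapped replicate 1 alone and 318 replicate 2 alone. The remaining 866 regions (13.8%) overlapped neither, and held 3.93% of the bases of the list. These had a median width of 1277 bp and a median score of 0.35, beside 4181 bp and 0.86 for the regions seen in both. The narrowest region of the replicate set was 1001 bp wide, and 457 of the 866 were narrower than the 1301 bp at which both replicate lists end. In the other direction, 13 regions of replicate 1 and 1 region of replicate 2 overlapped no region of the set.

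The second comparison is between chromosomes. The mark was spread over all 5 large arms, with 2R at the top and 2L at the bottom. On 2R, regions covered 23.6% ± 1.00 of the arm, and on 2L 18.5% ± 0.679 (SD, n = 2). On X it was 22.6% ± 1.05. Replicate 1 covered more than replicate 2 on both 2R (24.4% and 22.9%) and X (23.4% and 21.9%), and 2R lay above X in each. The values were 21.6% ± 0.736 on 3L and 21.4% ± 1.04 on 3R. Region density was 48.5 ± 0.736 per Mb on 2R, 47.1 ± 0.202 on 3L, 46.3 ± 1.22 on 3R, 41.5 ± 1.17 on X and 40.4 ± 0.860 on 2L. The small chromosome 4, which is rich in heterochromatin, had 45.1 ± 2.09 regions per Mb, within the range of the large arms. Its regions were narrower, with a median of 2539 ± 136 bp beside 3040 ± 12.0 bp on 2L, the lowest large arm. They covered 14.8% of the chromosome in each replicate.

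Among listed regions, those on the X scored higher and were wider than those on the autosomes. The threshold behind the lists is unknown, and sites that were not listed do not enter this comparison. In replicate 1 the median score was 1.01 on X and ran from 0.76 (3L) to 0.86 (2R) on the autosomal arms. In replicate 2 it was 0.97 on X and ran from 0.77 (3L) to 0.84 (chromosome 4). The median width was 3569 ± 210.0 bp on X and 3089 ± 36.1 bp over the autosomal arms (SD, n = 2). Over 500-kb windows of both-replicate regions, the mean score was 1.11 ± 0.12 in 45 windows of the X and 0.95 ± 0.12 in 196 autosomal windows (SD). The difference of 0.16, which is 1.12-fold, had a permutation p of 1e-05, the smallest that this test can give, and 4e-05 after adjustment. It was as large in 5 of 241 rotations of the X block along the genome, the unrotated position included. In both-replicate regions, the score of a region that the other replicate divides enters several times. Within the list of each replicate, where each region enters once, the difference was 0.17 (replicate 1) and 0.14 (replicate 2), and in the replicate set it was 0.11. The mean log2 width, into which short stretches of overlap also enter, differed by 0.15, or 1.11-fold (permutation p = 0.0033, adjusted 0.0065, 2 of 241 rotations), and by 0.22 in 100-kb windows. In the lists of single replicates, where no region is under 1301 bp, it differed by 0.25 (replicate 1) and 0.15 (replicate 2). Covered share was 20.6% ± 8.48 in X windows and 19.4% ± 8.84 in autosomal windows, a difference of 1.21 percentage points that did not pass the test (permutation p = 0.40, adjusted 0.40). The number of regions per window was 20.5 ± 7.82 on X and 21.9 ± 8.23 on autosomes (permutation p = 0.30, adjusted 0.40). Among the higher-scoring 50% of each replicate, the difference in score was 0.066 (permutation p = 0.0018, not adjusted), as large in 23 of 240 rotations, and the difference in log2 width was 0.029 (permutation p = 0.62). There the X windows were covered by 3.19 percentage points more than the autosomal windows (permutation p = 0.012, not adjusted), as large in 39 of 241 rotations. This selection is by score, which was higher on X, and it kept 62.3% of the X regions and 47.4% of the autosomal regions of replicate 1, so greater X coverage follows in part from the selection itself.

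**Figure D2:**
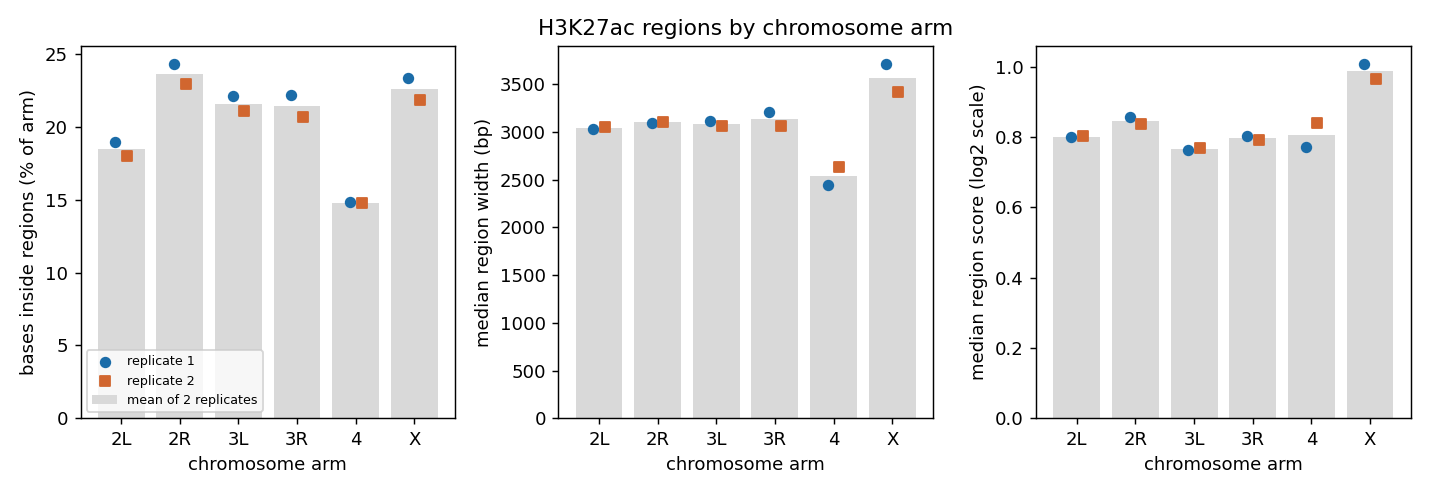
Percent of each chromosome arm inside enriched regions (left), median region width in bp (middle) and median region score on a log2 scale (right) for the 6 main arms, with points for each replicate and bars for their mean. The X has the highest median score (0.99) and width (3569 bp), and chromosome 4 the lowest covered share (14.8%) and width (2539 bp).

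The sequences assigned to heterochromatin (2LHet, 2RHet, 3LHet, 3RHet, XHet and YHet) and the unplaced sequence U held few regions. Together they spanned 19.3 Mb and carried 68.5 ± 2.12 regions (SD, n = 2), which covered 0.938% ± 0.025 of them, beside 21.4% ± 0.892 of the 6 main arms. These are shares of all bases, and how many of the bases reads could be placed on is unknown. The low share is therefore not a measure of how scarce the mark is there. Of the regions on heterochromatic and unplaced sequences, 62 of 70 in replicate 1 and 61 of 67 in replicate 2 overlapped the other replicate. Their median score was 0.98 in replicate 1 and 0.93 in replicate 2, beside 0.84 and 0.82 on the main arms. Their median width was 2435 ± 18.7 bp, beside 3157 ± 39.6 bp. XHet had the highest covered share of this group, 4.98% ± 0.390, from 4 regions in each replicate, and U the lowest, 0.519% from 21 regions in each.

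**Figure D3:**
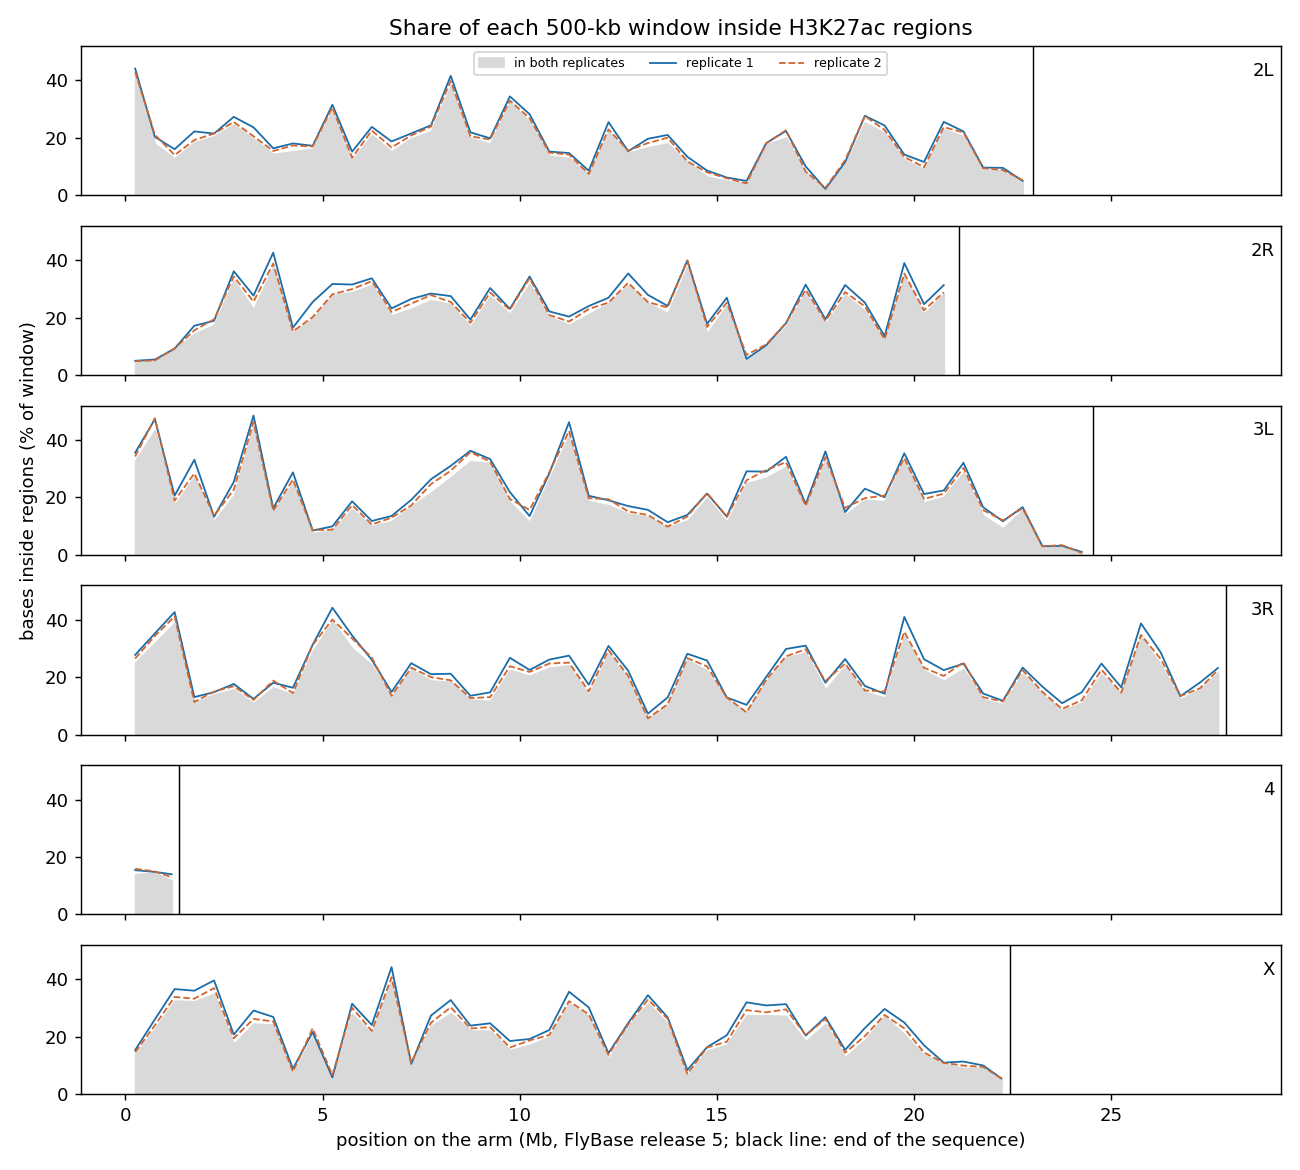
Percent of each 500-kb window (y axis) inside regions of replicate 1, replicate 2 or both, along the 6 main arms (x axis, Mb, FlyBase release 5). The highest window lies on 3L from 3000001 to 3500000, with 44.8% of its bases in both-replicate regions, and the lowest on 3L from 24000001 to 24500000, with 0.641%.

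The third comparison asks which both-replicate regions were the widest. A site that either replicate divides into several regions is divided here too, so the order can differ from that of each list. The widest 5% of the both-replicate regions were 265 regions of at least 12.6 kb and held 21.2% of the bases. Of these, 58 lay on X, 54 each on 2R, 3L and 3R, and 45 on 2L. None of the 57 regions of chromosome 4 was among them, which allows a share of up to 5.26%, and none of the 62 on heterochromatic and unplaced sequences, which allows up to 4.84%. The X held 21.9% of the wide regions and 17.5% of all both-replicate regions, a difference that was not tested.

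The widest both-replicate region lay on 3R from 12030014 to 12086198, and was 56.3 kb wide in replicate 1 and 56.4 kb in replicate 2, with scores of 2.18 and 2.17. The region on X from 12608400 to 12658277 was 50.9 ± 1.51 kb wide (SD, n = 2), with scores of 2.21 and 2.23. On 2R, the region from 6401151 to 6448706 measured 47.6 ± 0.108 kb and scored 1.94 and 1.87. At a pair of sites the listed widths differed between replicates. The region on 2R from 3626548 to 3671783 belonged to a region of 64.7 kb in replicate 1 and of 45.2 kb in replicate 2. The region on 2L from 12455123 to 12499831 belonged to one of 44.8 kb in replicate 1 and of 63.9 kb in replicate 2. That replicate 2 region also overlapped another replicate 1 region, which scored 1.60, so replicate 1 divided the stretch. In the 2L windows from 12000001 and from 12500001, replicate 2 covered 22.9% and 15.5%, and both-replicate regions 22.2% and 14.8%. The replicate set listed the sites on 2R and 2L as 64.9 kb and 64.7 kb, and the region on 3R named first as 60.8 kb. The others among the 10 widest lay on X from 6865970 to 6909074 (45.4 ± 3.19 kb), on 3R from 17446561 to 17487455 (41.0 ± 0.031 kb), on 3L from 8660937 to 8699642 (38.9 ± 0.052 kb), and on 2R from 12691414 to 12729870 (38.5 ± 0.074 kb) and from 7060426 to 7096886 (37.2 ± 0.405 kb). The lowest score among the 10 was 1.34 in replicate 1 and 1.26 in replicate 2, above the upper quartile of each list (1.24 and 1.19).

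The highest scores of the replicate set lay in narrow regions. The highest, 3.72, was on U from 7869574 to 7871918, where replicate 1 had a region of 1669 bp with a score of 3.90 and replicate 2 had none. The next 4 regions shared the score of 3.26 exactly, were 1001 to 1059 bp wide, and overlapped no region of either replicate. They lay on 3L from 8491434 to 8492492, on 3R from 4399802 to 4400802, and on U from 9260344 to 9261344 and from 9769786 to 9770798. Among regions that both replicates listed on the main arms, the highest by mean score lay on 3R from 7580643 to 7591020 (2.95 in replicate 1 and 2.55 in replicate 2) and on 3R from 27420370 to 27438297 (2.83 and 2.56). Both were chosen after their values were seen.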

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

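The comparisons of score and width on the X and the rotation of windows were added after the data had been seen, and the other alternatives were fixed before. No paired analysis was possible because it would set ChIP against input, and the input samples, which share replicate numbers with the ChIP samples, have no region list here. Arms could be compared within each replicate, where the covered share of X windows lay above that of autosomal windows by 1.48 percentage points in replicate 1 and 1.22 in replicate 2 (permutation p = 0.35 and 0.41). The alternatives that need genes (transcript starts, promoter widths, gene bodies, gene backgrounds and the share of marked genes on the X) were not run. Replicate overlap stayed above chance in every alternative tried, from 82.7% of replicate 1 regions with reciprocal overlap of 50% to 94.1% of replicate 2 regions among the higher-scoring 50%. The Spearman rho rose to 0.939 for scores and 0.943 for widths with reciprocal overlap. The higher score on X kept its direction and passed the permutation test in each replicate alone, in the replicate set, in the higher-scoring 50% and at both other window sizes, with differences of 0.066 to 0.187. The lowest is from the higher-scoring 50%, where the range of scores is shorter by construction and 23 of 240 rotations were as large. The greater width on X passed in these alternatives, at 0.15 to 0.25, except the higher-scoring 50%, where the difference was 0.029 (permutation p = 0.62). The covered share on X moved past the threshold in the higher-scoring 50% (3.19 percentage points, permutation p = 0.012), though 39 of 241 rotations were as large. Selecting by score kept 62.3% of X and 47.4% of autosomal regions in replicate 1, and 60.3% and 47.6% in replicate 2, so this value does not show greater X coverage apart from the scores. The sign turned for regions per window, at -1.42 (permutation p = 0.30). The causes of this change and of the smaller difference in width were not tested. The higher-scoring 50% held 2588 regions over 17.4 Mb, of which the widest 5% held 17.6%. Covered length was 25.2 to 26.8 Mb with either replicate left out and 30.5 Mb in the replicate set. The share of bases in the widest regions was 23.0% for the replicate set, 32.9% for the widest 10% and 11.1% for the widest 2%. The listed widths of the regions on 2R and 2L that differed between replicates depended on the replicate. The region on 2R measured 64.7 kb in replicate 1 and 45.2 kb in replicate 2, and that on 2L 44.8 kb and 63.9 kb. On 2L the replicate 2 region overlapped another replicate 1 region as well, so the width there depended on how the stretch was divided. Without read counts, differences between weak regions cannot be weighed by depth.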

Other observations

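The tests of X scores by width, of replicate-set regions found in neither replicate and of tied scores were chosen after these patterns were seen. For the comparison of whole-number ratios in regions found in neither replicate, the outcome that would count was set before its result over the shared range of widths was seen, and the comparison within width classes, limited to classes that hold both kinds of region, was chosen after.

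Regions were sparse at the end of the arm sequence nearer the centromere on 2L, 2R, 3L and X. Sequences assigned to heterochromatin are listed apart from the arms, so this end need not adjoin the centromere. By the usual orientation of the arms, 2L, 3L and X run toward the centromere and 2R and 3R away from it. The 1 Mb at the end nearer the centromere was covered by regions to 7.14% ± 0.172 on 2L, 5.06% ± 0.159 on 2R, 2.30% ± 0.051 on 3L and 7.78% ± 0.206 on X (SD, n = 2). The opposite ends held 32.1% ± 0.164, 23.0% ± 1.34, 41.2% ± 0.346 and 20.0% ± 0.995. On 3R the order was turned, with 31.0% ± 0.762 at the first 1 Mb of the sequence and 17.9% ± 0.908 at the last. How far each arm sequence reaches toward the centromere was not compared. Sparse windows also lay within the arms, such as 2L from 17500001 to 18000000, where both-replicate regions covered 1.56%. The longest stretch of a main arm without a region in either replicate was 448 kb, on 2L from 16928825 to 17376361, in which the replicate set lists 4 regions, and the next was 364 kb, on X from 20534104 to 20897842. The densest windows were on 3L from 3000001 to 3500000 (44.8% covered in both replicates) and from 500001 to 1000000 (43.4%). The annotation of these positions was not used here, and how many of their bases reads could be placed on is unknown.

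The replicate set named 3 regions as depleted, on 3L from 10455220 to 10456952 with a score of -0.0052 and on 2R from 11088398 to 11090098 and from 15016480 to 15018204 with scores of -0.046 and -0.040. The lowest score of a region it named as enriched was 0.028. Replicate 2 listed more regions than replicate 1 on X (949 and 912) and fewer on each of 2L, 2R, 3L, 3R and 4.

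Regions on X had a median score 0.19 higher than those on autosomes in the both-replicate set, which holds listed regions only. The greater width of X regions was examined over 5 classes by width. Each class still holds a range of widths, so the role of width within a class stays open. Width differences between classes are not the whole cause, since within classes the score difference was still 0.11 on average (95% bootstrap over windows 0.08 to 0.13). This average was 0.09 in each replicate alone and smaller in the replicate set, at 0.06 (0.03 to 0.09), and the interval included 0 in the second widest class of replicate 1 (-0.05 to 0.16) and of the replicate set (-0.04 to 0.12) and in the widest class of replicate 1 (-0.0013 to 0.16). A factor common to all X regions, such as a copy number of X that differed between precipitated chromatin and reference, may explain it and stays open, since the difference in the widest class exceeded that in the narrowest by 0.0062 in the both-replicate set, with an interval of -0.07 to 0.08 that is too broad to settle whether the offset is even. The labels give no sex of the larvae, and no biological explanation was tested.

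Of the 866 regions of the replicate set found in neither replicate, 52.8% (95% Wilson interval 49.4 to 56.1) were narrower than the replicate lists allow. Whether the lower width limit also left out the others cannot be told, since a site may be narrower in a replicate than in the set. At widths from 1301 to 1999 bp the median score of the others was 0.32 in 368 regions, beside 0.26 in 199 regions seen in both replicates. The difference was 0.067 (bootstrap interval 0.05 to 0.08), and within the 4 of 5 width classes that held both kinds it was 0.09 (0.06 to 0.11). The listed scores of the former were thus not lower. Both groups hold listed regions only, so this cannot tell whether their enrichment was weaker than a replicate list keeps. The scores were ratios of whole numbers, with denominators of at most 400, in 74.5% and 39.2% of these regions, a difference of 35.3 percentage points (27.2 to 43.5), but such ratios are more frequent in narrow regions and the median widths were 1542 and 1871 bp. Within the 4 classes the difference was 33.3 points (18.3 to 47.5), without the class of only 9 regions seen in both it was 24.9 (13.8 to 35.8), and 114 regions in the narrowest class had no counterpart. For the regions that could be matched this is consistent with the hypothesis that they rest on fewer reads, which were not counted here; no biological explanation was tested.

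The tied score of 3.26 of 4 narrow regions of the replicate set equals 8 times, on the linear scale, the most common score of that list, 0.26, which 24 regions share. Such ratios of whole numbers made up 77.4% of the scores in the narrowest of 5 width classes and 8.69% in the widest. A candidate explanation is that the scores are ratios of few reads, for which the test value is the ratio of 8. No biological explanation was tested.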
